A study of Homo sapiens with 3 samples.

How the data were processed

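Chromatin immunoprecipitation with sequencing against TCF7L2 was carried out in the human trophoblast stem cell line CT27 in the stem cell state (TSC) and as extravillous trophoblast (EVT), the invasive cell type of the placenta. The series holds 3 samples: 1 TCF7L2 library per cell state and 1 input library. The state of each library was taken from its title and library name, because the cell type label of all 3 samples reads trophoblast stem cells. The title of the input also names IgG, so the kind of control is not settled by the labels. A peak list was analysed for each of the 2 TCF7L2 libraries, and none was used for the input.

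The submitters' processing notes name Bowtie2 2.4.5, MACS3 and the genome build hg38, with no role, setting or order, and whether the input served as the control of the peak calls is not given in the sources used here. Each library has its own list, so peaks were called per sample and not on pooled libraries. The deposited lists carry no header, and the meaning of their columns was worked out from the values. The deposited signal value is the pileup of fragments at the summit, in whole numbers of at least 15 in both lists. The deposited ratio is the fold enrichment of the summit over the local background, and it is above 5 for all peaks. The last deposited column is the −log10 q at the summit, with a lowest value of 6.05 in TSC and 6.40 in EVT. A background level computed from pileup and fold gave Poisson probabilities that ranked the peaks as the deposited −log10 q values do, with a Spearman coefficient over peaks of 1.000 in both lists when rounded. The files give no read totals, so the sequencing depth is unknown. Pileup, fold and −log10 q are the authors' values per peak and were used to describe, rank or filter peaks within a list. They were not compared between the lists, except for the lowest background level that pileup and fold imply, which served as a check of depth.

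Chromosomes 1 to 22 and X were used, which left out 15 entries of the TSC list and 39 of the EVT list. Positions are given as in the files (hg38), which do not state whether starts are counted from 0 or 1. Peaks of the lists were called shared when they overlapped by at least 1 bp, with bedtools 2.31.1 giving the same counts as the Python code. A TSC-only or EVT-only peak had no such overlap with a peak of the other list. The overlap was set against 100 random placements of the other list on the same chromosomes. Shares have 95% Wilson intervals, which cover counting error over peaks and treat peaks as independent.

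Each summit was assigned to the nearest protein-coding gene body within 100 kb, among 19974 genes of the RefSeq table (GRCh38.p14). Summits inside several genes went to the gene with the nearer end. The table gives gene starts and ends without strand or exons. The planned share of peaks at transcription start sites was therefore left out, and the share of summits within 1 kb of either gene end took its place. Assignment to the nearest transcription start site was replaced by assignment to the nearest gene body. The planned counts of sequence motifs at summits were left out because no genome sequence was used here. No exon or intron is given for any peak, because the gene table holds no exons.

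The 12 gene lists were fixed before the data were examined: trophoblast stem cell and cytotrophoblast, extravillous trophoblast, syncytiotrophoblast, Wnt feedback and target genes, Wnt ligands with receptors and core machinery, Hippo and TEAD, epithelial-mesenchymal transition and matrix, NOTCH and TGF-beta, cell cycle, placental stroma with endothelium and macrophage, neuron, and hepatocyte. All members were found in the gene table, and some belong to several lists. For each list the number of members with a TSC peak, the number with an EVT peak, and the number with an EVT-only peak minus the number with a TSC-only peak were ranked among 10000 random lists. The random lists had the same size and were matched on decile of the length of genome assigned to each gene, measured on a grid of 1 kb. A percentile above 97.5 or below 2.5 was treated as outside the middle 95% of random lists. Percentiles describe these libraries, since genes are not replicates and no p-value can be given with 1 library per group. The share of a list's EVT peaks that were EVT only, and the number of members with an EVT peak and no TSC peak, were added after the data were seen.

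The genes named in the text follow a rule fixed before the data were examined. It takes members of the gene lists, the 5 peaks with the highest fold in each class (shared peaks by the worse of their ranks in the lists, TSC-only peaks and EVT-only peaks), the 10 genes with the most EVT-only peaks, the 5 with the most TSC-only peaks, and TCF7L2. Other genes are named with the statement that they were chosen after their values were seen.

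Several of the steps were tested on simulated data. The difference between members with an EVT-only and with a TSC-only peak was not simulated. Of 23813 simulated TSC peaks, 60.1% were put on EVT peaks and 60.4% were found overlapped. With peaks placed at random, 17 of 200 random lists of 30 genes fell outside the middle 95%, more than the 5% intended. Of 40 lists of 30 genes drawn from genes of which about 50% had been given an extra EVT peak, 30 lay above percentile 97.5. The share test put all 40 seeded lists above that percentile and 3 of 40 other lists outside the middle 95%.

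The alternatives were a −log10 q of at least 5, the upper 50% of each list by fold, the same number of strongest peaks from each list, overlap of at least 50% of the peak, summits within 200 bp, shifts of 50 to 500 kb in place of random placement, and −log10 q in place of fold. For the gene lists they were also a limit of 10 kb, counting a peak for any gene within 50 kb, and random lists of genes with a peak in either list, planned for the difference and extended to the counts of members with a peak after the data were seen. A fold of at least 10 and the settings for gene ends (2.5 kb, ends of all annotated genes) were added after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.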

Results

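TCF7L2, a DNA-binding partner of beta-catenin in the Wnt pathway, was profiled by ChIP-seq in CT27 human trophoblast stem cells (TSC) and in extravillous trophoblast (EVT), the invasive lineage that anchors the placenta. The study asks how TCF7L2 acts in self-renewal and in differentiation of these cells. There was 1 TCF7L2 library per state, so differences between the lists have no replicate check and no p-value is given. Read totals were not in the files, and the depth of each library is unknown.

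More TCF7L2 peaks, at more genes, were called in EVT than in TSC. The EVT list held 49842 peaks over 12.9 Mb and the TSC list 23813 peaks over 6.09 Mb, a ratio of 2.09 in number. Of 19974 protein-coding genes, 10854 (54.3%) had an EVT peak and 7398 (37.0%) a TSC peak. Both lists had a peak at 6878 genes, EVT alone at 3976 and TSC alone at 520. The list lengths bear on these numbers. In random lists matched to the 28 genes of the stem cell list, a mean of 19.8 had an EVT peak and 14.1 a TSC peak. With the same number of strongest peaks from each list, the EVT mean was 15.1. The TCF7L2 gene itself had 17 peaks in each list, of which 5 in each were called in that list alone. Its strongest TSC peak lay inside the gene at chromosome 10, 112957921 to 112958230, with a fold enrichment of 24.8. Peaks had a median width of 228 bp in TSC and 230 bp in EVT, with quartiles of 178 and 302 bp and of 181 and 304 bp. The median pileup was 27 fragments in TSC and 25 in EVT.

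The strongest TSC sites were mostly kept in the EVT list. The shared peak that ranked highest in both lists lay 4.50 kb from MPP7, a scaffold protein of cell junctions, at chromosome 10, 28339337 to 28340124 in TSC, with a fold of 105 in TSC (rank 4) and 101 in EVT (rank 1). The next lay inside KCTD7 (chromosome 7, 66639774 to 66640182), 32.9 kb from UBE2L5 (chromosome 13, 30389409 to 30389764), more than 100 kb from any protein-coding gene (chromosome 13, 106736935 to 106737302), and 46.3 kb from the glucose transporter gene SLC2A3 (chromosome 12, 7982266 to 7982789). Of the TSC peaks, 16789 were overlapped by an EVT peak (70.5%, interval 69.9 to 71.1), against a mean of 0.859% for randomly placed EVT peaks. Of the EVT peaks, 16715 were overlapped by a TSC peak (33.5%, interval 33.1 to 34.0), against 0.410%. Summits of shared peaks lay a median of 18 bp apart. The list lengths bound these shares: with the same number of strongest peaks from each list, they were 49.2% of TSC and 48.7% of EVT peaks.

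Overlap rose with peak strength in both lists. In the top fold decile 93.5% of TSC peaks (interval 92.5 to 94.5) and 74.4% of EVT peaks (interval 73.2 to 75.6) had a partner, against 57.1% and 15.7% in the lowest decile. The median fold of TSC peaks was 12.8 (quartiles 8.70 and 21.2) for shared and 9.21 (7.61 and 12.7) for TSC-only peaks. Within the EVT list it was 14.9 (9.86 and 23.5) for shared and 9.33 (7.48 and 12.8) for EVT-only peaks.

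**Figure D1:**
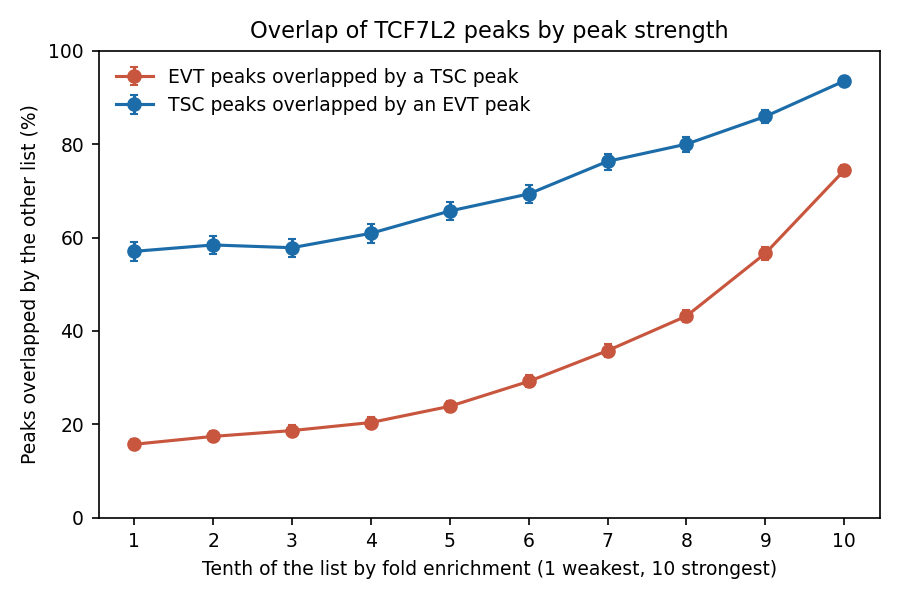
Percent of TCF7L2 peaks overlapped by a peak of the other list (y axis) in each decile of a list ranked by fold enrichment (x axis, 1 weakest, 10 strongest), for the TSC list and the EVT list; bars are 95% Wilson intervals. The share is 93.5% in TSC and 74.4% in EVT at the strong end, and 57.1% and 15.7% at the weak end.

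Strong peaks of a single list were also present. The strongest TSC-only peak lay inside TACC1, a gene of a centrosomal coiled-coil protein (chromosome 8, 38786938 to 38787283; fold 94.1, rank 25 in TSC), with the nearest EVT summit 1.55 kb away. The others lay inside PCDH11X (fold 76.8), 86.7 kb from the potassium channel gene KCNQ5 (71.2), 3.24 kb from AHDC1 (69.0), and far from genes at chromosome 2, 52192679 to 52193031 (86.5). The strongest EVT-only peak lay inside LMNTD1 (chromosome 12, 25510934 to 25511586; fold 70.6, rank 79 in EVT). It was followed by peaks 9.20 kb from ITPKB, an inositol phosphate kinase gene (69.7), 11 kb from RAP2B, a small GTPase gene (67.6), and at sites more than 100 kb from genes on chromosome 21 (67.9) and chromosome 8 (67.6).

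Genes of the trophoblast stem cell and cytotrophoblast list were occupied in both states. Of 28 members, 27 had a TSC peak, against a mean of 14.1 in random lists (percentile 100), and 26 had an EVT peak, against 19.8 (percentile 99.9). Among lists of genes with a peak in either list, the TSC count stayed at percentile 100. The EVT count there was 26 of 27 measured members, against a mean of 25.9 (percentile 47.4). With so little room above the mean, that setting says little about the EVT count. The transcription factor genes TP63 (13 TSC and 17 EVT peaks), TEAD1 (18 and 20), GATA3 (10 and 13), TFAP2C (8 and 7) and KLF5 (12 and 20) had peaks in each. The strongest TSC peak near GATA3 lay 29.5 kb away at chromosome 10, 8104522 to 8105308, with a fold of 89.0, and was shared. KRT8 (6 and 5), KRT18 (5 and 3), LRP2 (12 and 9) and ARID3A (7 and 5) were among the 6 members with more TSC than EVT peaks, and 21 members had more EVT peaks. This turned to 19 members with more TSC and 6 with more EVT peaks with the same number of strongest peaks from each list. ITGA6, an integrin gene of villous cytotrophoblast, had 2 TSC and 14 EVT peaks, and EGFR had 8 and 20. SPINT1 had no peak, and BCAM had 1, in TSC. Of the 240 EVT peaks of this list 51.3% were EVT only, against a mean of 66.3% in random lists (percentile 1.21). With the same number of strongest peaks from each list this share was 36.1% at percentile 5.83, inside the middle 95%. Of the 167 TSC peaks of the list 28.1% were TSC only, against 28.6% in random lists (percentile 49.1).

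Of the 36 genes of the extravillous trophoblast list, 12 had a peak in the EVT list and none in the TSC list, against a mean of 8.16 in random lists (percentile 93.1, inside the middle 95%). The neuron and hepatocyte lists had 5 such members of 18 each, and the reverse held for 0 extravillous members. The stem cell list, with a TSC peak at 27 of 28 members, had 0 members with an EVT peak and no TSC peak. Its random mean was 6.47 (percentile 0.035), or 3.41 with the same number of strongest peaks (also 0 members, percentile 1.3). The 27 members with a TSC peak, in both settings, left almost no room for such members. These percentiles therefore restate the TSC count and are no separate result. The extravillous count was 7, against 4.25, with the same number of strongest peaks from each list (percentile 91.0). In all, 29 members had an EVT peak, against a mean of 22.8 in random lists (percentile 99.3), and 17 a TSC peak, against 15.6 (percentile 69.3). Among lists of genes with a peak the EVT count was at percentile 87.5, with 29 of 29 measured members. That was the highest count possible, so that setting could not test the EVT count. ADAM12, a metalloprotease gene, had 12 EVT peaks (10 inside the gene), the pregnancy-associated protease gene PAPPA2 11 (2 inside) and the deiodinase gene DIO2 8 (5 inside). ITGA5, JAM2, PAPPA and EBI3 had 3 each, with a strongest fold of 6.13, 17.0, 25.5 and 7.14. The values for ITGA5 and EBI3 fall in the weakest EVT decile and the next, where 84.3% and 82.6% of all EVT peaks were EVT only. ITGA1, the EVT integrin gene, was assigned 10 EVT peaks and no TSC peak, but a further peak inside it, shared by both lists (chromosome 5, 52790487 to 52790822 in TSC), was assigned to the overlapping gene PELO. The HLA-G gene, a marker of EVT, had 1 TSC and 3 EVT peaks, with its strongest EVT fold at 9.45. EPAS1 had 10 and 20, FN1 5 and 11, MMP2 2 and 4, and ASCL2 2 and 5, whereas MMP11, MMP12, HTRA1, HTRA4, AOC1, NOTCH1 and LVRN had no peak in either list. Members with an EVT-only peak (27) outnumbered those with a TSC-only peak (9), a difference of 18 against 12.3 in random lists, inside their middle 95% (percentile 95.5). With a limit of 10 kb between peak and gene it was at percentile 99.1, and among lists of genes with a peak at 81.4. It was at 75.01 with the same number of strongest peaks from each list, where 15 members had an EVT-only and 12 a TSC-only peak. The high number of members with an EVT peak depended on the weaker EVT peaks: with the same number of strongest peaks from each list its percentile was 78.8.

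Genes of the Wnt feedback and target list were bound in both states, with a low share of EVT-only peaks but not of TSC-only peaks. The list also holds cofactor genes of the pathway: TLE1, TLE3, TLE4, BCL9, BCL9L and PYGO2. A TSC peak was found at 27 of 34 members, against a mean of 18.6 in random lists (percentile 99.96). An EVT peak was found at 31, against 24.9 (percentile 99.7, or 96.0 when a peak counted for any gene within 50 kb). The EVT count was at 82.3 among lists of genes with a peak, where 31 of 31 measured members was the highest count possible. That setting could therefore not test the EVT count. AXIN2, the negative feedback gene of the pathway, had 13 TSC and 21 EVT peaks. The strongest in TSC lay at chromosome 17, 65560279 to 65562163, inside the gene with a fold of 79.6. The ubiquitin ligase genes ZNRF3 and RNF43, which remove Wnt receptors, had 26 and 11 TSC peaks and 22 and 9 EVT peaks, and the ZNRF3 peak with the highest TSC fold (66.5, chromosome 22, 29004572 to 29004938) was TSC only. MYC had 17 and 23, TLE4 21 and 19, LGR5 6 and 7, NKD1 4 and 2, and SP5 1 in each list. The Wnt inhibitor genes SFRP1 (11 EVT peaks, 1 inside the gene) and DKK1 (4, with 0 inside) had no TSC peak. EVT-only peaks were 116 of the 241 EVT peaks of the list (48.1%), against a mean of 66.3% in random lists (middle 95% from 55.7 to 76.9, percentile 0.05). With the same number of strongest peaks from each list the share was 32.8% against 51.0% (percentile 0.975). In that setting 134 of the 241 EVT peaks remained, against 59 of 138 for the extravillous list. The EVT-only share of all EVT peaks fell from 84.3% in the weakest fold decile to 25.6% in the strongest. The random lists of this share, for all gene lists, were not matched on peak strength, so its part in the low share was not separated. Of the 185 TSC peaks of the list 31.9% were TSC only, against 28.8% in random lists (percentile 69.3). With the same number of strongest peaks from each list that was 50.8%, against 50.2% (percentile 53.4). In the full lists 18 members had more EVT and 6 more TSC peaks, and with equal numbers of peaks 7 and 16.

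**Figure D2:**
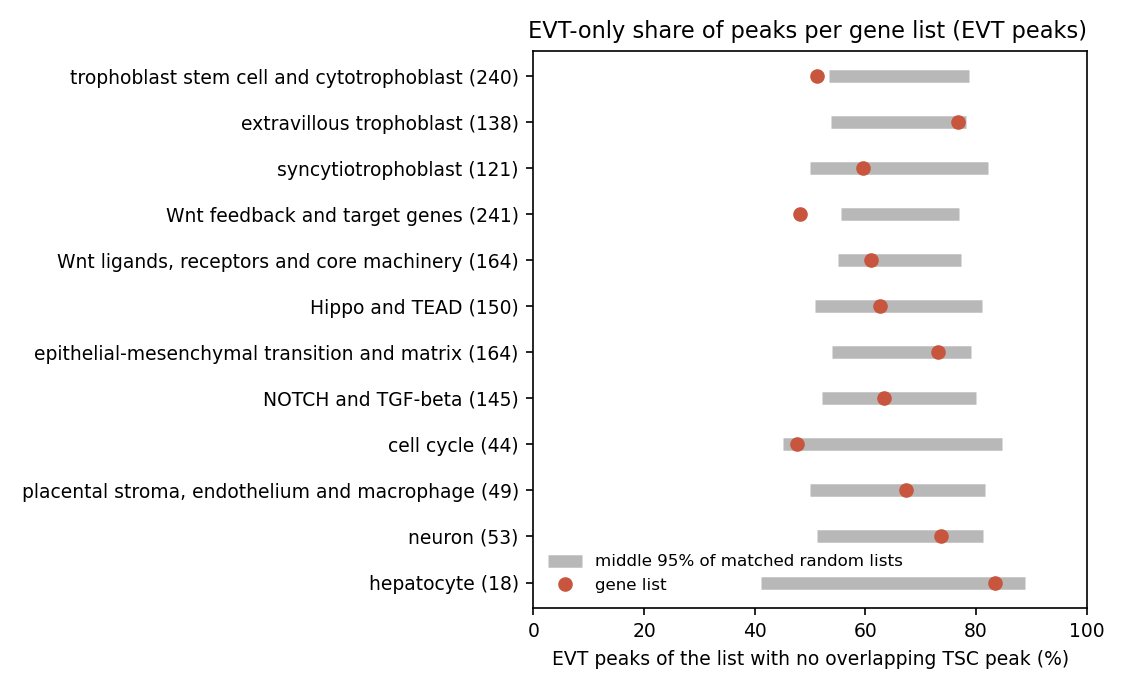
Percent of the EVT peaks of each gene list that had no overlapping TSC peak (x axis; points), with the middle 95% of 10000 random lists matched on gene neighbourhood (grey bars); the number of EVT peaks stands beside each list. The Wnt feedback list (48.1%) and the trophoblast stem cell list (51.3%) lie below their bars, and the extravillous list lies at 76.8%, inside its bar.

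Wnt ligands, receptors and core machinery had peaks in both states. A TSC peak was present at 28 of 40 members, against a mean of 18.0 in random lists (percentile 99.98, or 95.5 in the upper 50% of each list), and an EVT peak at 37, against 25.7 (percentile 100). Among lists of genes with a peak these counts were at 92.7 and 91.3. The EVT count there was 37 of 37 measured members, the highest possible, so that setting could not test the EVT count. With the same number of strongest peaks from each list, 28 members had a TSC peak and 27 an EVT peak. CTNNB1, which encodes beta-catenin, had 8 EVT peaks and no TSC peak, and 0 of the 8 lay inside the gene. The strongest lay at chromosome 3, 41199341 to 41199574, 0.06 kb from the gene. WNT7A had 4 TSC and 18 EVT peaks, and WLS, which carries Wnt proteins to the cell surface, 9 and 16. APC had 6 and 10, and the receptor gene LRP6 0 and 4. In all, 27 members had more EVT peaks. The 4 with more TSC peaks were WNT6 (3 and 2), WNT7B (3 and 2), WNT9A (4 and 3) and PORCN (2 and 1). With the same number of strongest peaks from each list, 17 members had more TSC and 9 more EVT peaks. Members with an EVT-only peak (32) exceeded those with a TSC-only peak (11) by 21, against 13.6 in random lists (percentile 98.5), but with the same number of strongest peaks from each list the percentile was 9.42.

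Hippo and TEAD genes had peaks at 16 of 20 members in TSC (random mean 10.04, percentile 99.8) and at 19 in EVT (14.0, percentile 99.7). Among lists of genes with a peak the percentiles were 94.0 and 76.6. The EVT value came from 19 of 19 measured members, the highest count possible, so that setting could not test the EVT count. The coactivator genes YAP1 (8 TSC and 12 EVT peaks) and WWTR1 (4 and 13), and VGLL3 (2 and 13), had more peaks in EVT, as did 18 members in all, and no member had more in TSC. With the same number of strongest peaks from each list, 16 members had a TSC and 14 an EVT peak (percentile 94.3), and 8 had more TSC and 5 more EVT peaks. Syncytiotrophoblast genes had a TSC peak at 16 of 30 members (random mean 9.96, percentile 99.5, or 87.1 with a limit of 10 kb) and an EVT peak at 23 (14.7, percentile 99.97). Among lists of genes with a peak their TSC count was at 77.9. Their EVT count was at 86.0, again its ceiling, with 23 of 23 measured members. GCM1, the master regulator of trophoblast fusion, had 6 and 11 peaks, PSG3 2 and 9, and the hormone subunit gene CGA 0 and 3. The placental endogenous retroviral envelope gene ERVW-1 had 1 shared peak.

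The remaining lists lay inside the middle 95% of random lists for all of the 3 counts. For epithelial-mesenchymal transition and matrix, 18 of 28 members had a TSC peak (percentile 94.9) and 23 an EVT peak (94.5). Within it PLAU, a protease gene of invasion, had 0 TSC and 8 EVT peaks, with 0 of the 8 inside the gene. The laminin gene LAMC2 had 1 and 7, COL4A1 2 and 14, ITGB1 4 and 13, and SERPINE2 1 and 9. In all, 17 members had more EVT peaks (8 with the same number of strongest peaks, and 9 then had more TSC peaks). The 4 with more TSC peaks were CDH2 (5 and 4), TIMP2 (5 and 3), SNAI2 (2 and 1) and SERPINE1 (3 and 2). For NOTCH and TGF-beta, 15 of 25 members had a TSC peak (percentile 90.4) and 21 an EVT peak (96.4). TGFB2 had 1 and 20, SMAD3 11 and 26, and TGFBR2, with more TSC peaks, 11 and 8. Cell cycle genes had a TSC peak at 10 of 22 members (93.0) and an EVT peak at 13 (87.4), with CDK6 (10 and 12) and CCNE1 (8 and 10) carrying the most. Of the lists of other tissues, placental stroma, endothelium and macrophage had 10 and 13 of 22 members with a peak (percentiles 53.8 and 33.3), neuron 6 and 10 of 18 (3.68 and 4.93), and hepatocyte 5 and 8 of 18 (40.8 and 34.0). In total 13 of 36 percentiles fell outside the middle 95%, over lists that share members.

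The difference of members with an EVT-only and with a TSC-only peak was ranked low for the stem cell list (3, against 10.4 in random lists, percentile 0.96), and lay inside the middle 95% in the upper 50% of each list (7.31), with a limit of 10 kb (20.1) and at a fold of at least 10 (48.4). It was at percentile 2.77 for Wnt feedback genes. For these it was at 0.485 among lists of genes with a peak, 27.6 with the same number of strongest peaks and 62.7 in the upper 50%. Syncytiotrophoblast genes were at 87.5, Hippo and TEAD genes at 60.4 and epithelial-mesenchymal transition genes at 8.88. NOTCH and TGF-beta genes were at 82.8, cell cycle genes at 37.5, stroma at 19.4, neuron at 56.7 and hepatocyte genes at 33.8. A member with both kinds of peak cancels out in this difference. That held for 18 of 28 stem cell, 18 of 34 Wnt feedback and 8 of 36 extravillous members. The random lists were not matched on the number of peaks, so its part in the low ranks was not separated.

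**Figure D3:**
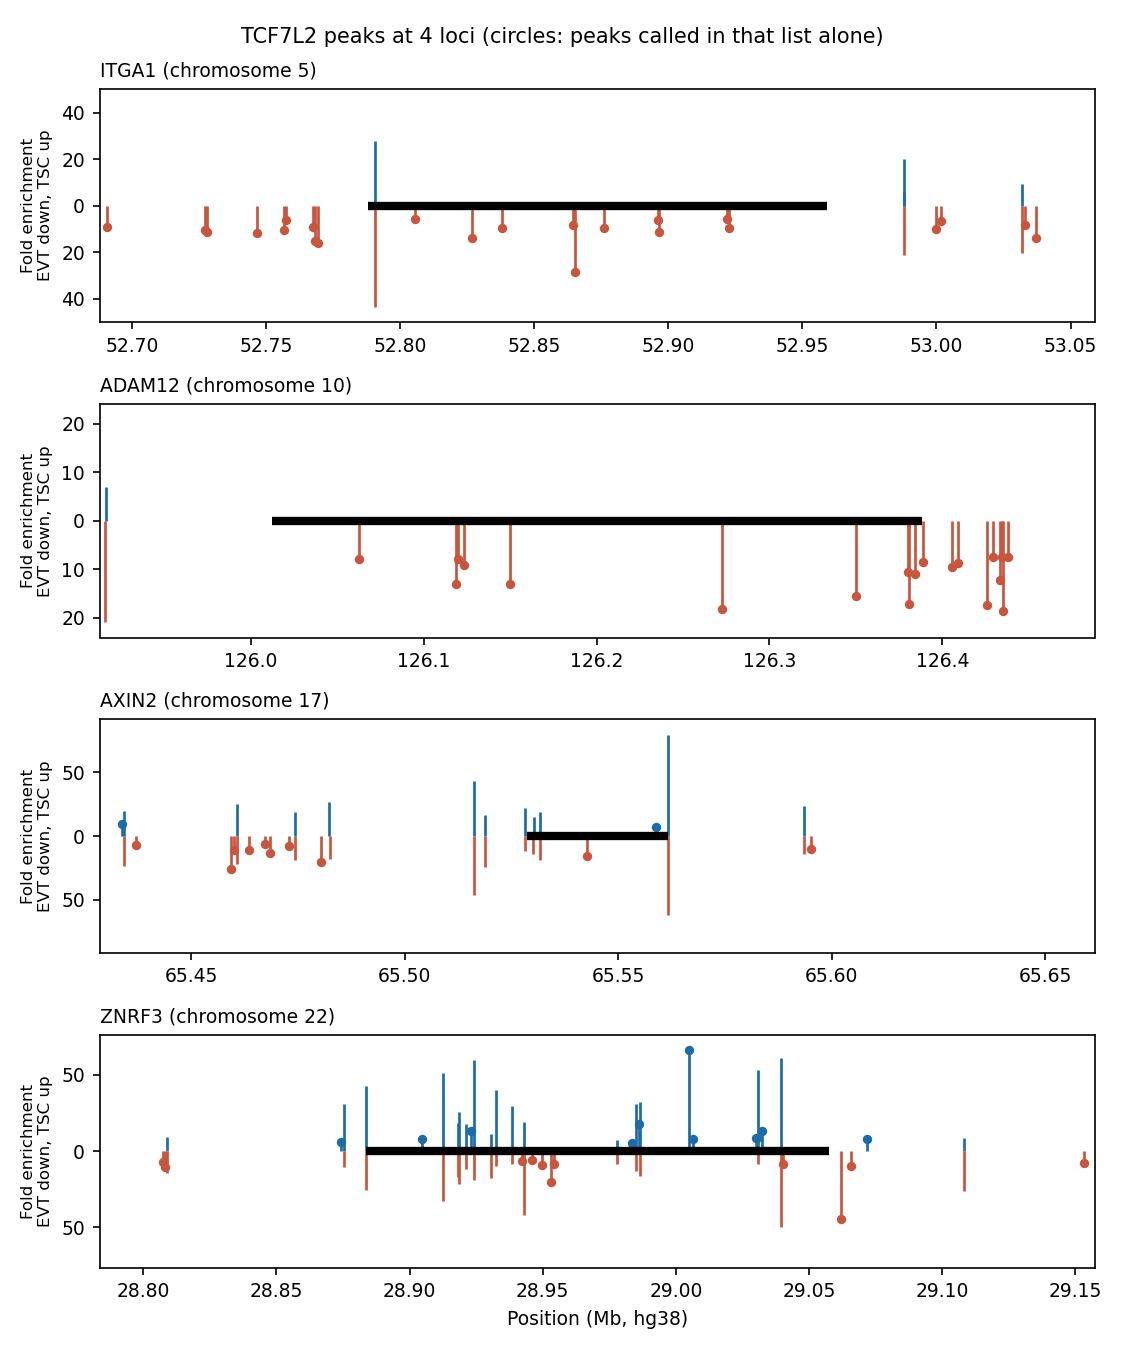
TCF7L2 peaks from 100 kb before to 100 kb after ITGA1, ADAM12, AXIN2 and ZNRF3; x axis position in Mb (hg38), black bar the gene, lines at summits with a height of the authors' fold enrichment, TSC upward and EVT downward, and circles on peaks called in that list alone. Heights are to be read within a list. ADAM12 was assigned 12 EVT-only peaks, and the shared peak inside ITGA1 is the PELO peak, whereas AXIN2 and ZNRF3 carry shared peaks along with those of a single list.

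The genes with the most EVT-only peaks were mostly long. The neuron navigator gene NAV2 had 29 EVT-only peaks of 38, SMYD3 26 of 31, INPP4B, a phosphoinositide phosphatase gene, 25 of 31, the formin gene FHOD3 25 of 25, and PTPRM 25 of 39. DLG2 had 23, STARD13 22, and DMD, ADGRV1 and TENM3 21 each, and these 10 genes were 483 to 2220 kb long. The most TSC-only peaks were assigned to ZFHX3 (12 of 33), ZNRF3 (10 of 26), ADGRL2 (10 of 17), LRP1B (9 of 18) and SETBP1 (9 of 19). Of these ZNRF3 is the shortest, at 174 kb.

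TCF7L2 summits lay inside or near protein-coding genes more often than positions of the genome in both lists. They lay inside a gene for 46.3% of TSC peaks (interval 45.6 to 46.9) and 48.3% of EVT peaks (47.9 to 48.7). Of positions on a 1 kb grid of the genome 41.7% did. Unsequenced stretches, where no peak can be called, are part of the grid and can lower its share inside genes. Their part in the small excess was not separated. Summits within 1 kb of a gene end made up 5.10% in both lists, against 2.397% of grid positions, and 4.39% of EVT peaks with the same number of strongest peaks from each list. The share was 5.59% (5.25 to 5.94) for shared, 4.84% (4.61 to 5.07) for EVT-only and 3.94% (3.51 to 4.42) for TSC-only peaks. Peaks more than 100 kb from any protein-coding gene made up 16.0% of each list, against 31.4% of the grid, which also includes unsequenced stretches.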

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

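The tests of the number of peaks were chosen after that result was seen, and the tests of the other patterns before their results were seen. Peaks on contigs outside the assembled chromosomes were used in no comparison: the TSC list held 12 and the EVT list 38, above the 3 that a count of 0 allows.

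The EVT list held 2.09 times as many peaks as the TSC list. The lowest background level implied by pileup and fold was 1.04 times as high in EVT as in TSC, and the narrowest peaks were 120 bp in TSC and 121 bp in EVT, which argues against a much deeper EVT library as long as pileups were not rescaled before deposit. Joining peaks of a list less than 1 kb apart left 2.06 times as many regions in EVT as in TSC, and less than 5 kb apart 1.98 times, which argues against broad EVT peaks split into several. In the top decile of EVT peaks by fold, 25.6% had no TSC peak, which argues against TSC sites just below the calling threshold as the whole explanation and leaves open that they account for weaker EVT-only peaks. A change of cell state and a more efficient immunoprecipitation in the EVT library cannot be told apart with 1 library per state.

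Genes of the extravillous trophoblast list more often had an EVT-only than a TSC-only peak, and the difference stood at percentile 95.5 among random lists matched on neighbourhood length, inside their middle 95%. With the same number of strongest peaks from each list it was at percentile 75.01, so the length of the EVT list may account for it. Under that setting the stem cell list was at percentile 2.08, the direction a link to cell state would need, but it was at 7.31 in the upper 50% of each list, 20.1 with a limit of 10 kb and 48.4 at a fold of at least 10. A link to cell state stays open, since 1 library per state leaves state and library confounded.

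Among 904 genes with at least 10 EVT peaks, 100 had at least 90% of them EVT only. Shuffling the EVT-only label 1000 times within fold deciles gave a mean of 41.8 such genes and a highest count of 60, so scatter of weak peaks among genes did not account for the number. Of the EVT peaks within 1 Mb assigned to genes outside these 100, 66.9% were EVT only (interval 65.3 to 68.5), against 66.5% of all EVT peaks. This argues against gains of regions in the EVT culture that take in those other genes. Neighbours that were themselves among the 100 were left out, so the share cannot decide about gains that cover adjoining genes of the 100. The shuffles treat neighbouring peaks as independent, and blocks of chromatin that open in EVT are a candidate explanation that was not tested with these files. FHOD3 (25 of 25 EVT peaks EVT only), ROBO1 (21 of 22), RGS6 (20 of 21) and TGFB2 (19 of 20) were among these genes, and ROBO1 and RGS6 were chosen after their values were seen.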

How the results depend on the processing

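No paired analysis was possible because each group has 1 library and the labels give no replicate number. A −log10 q of at least 5 removed no peak, so it tests nothing. The settings with a fold of at least 10, those for gene ends, those for the share of EVT-only peaks and for members with an EVT and no TSC peak, and counts of members with a peak set against genes with a peak were chosen after the data were seen, and the others before. The settings for transcription start sites and motifs were not run. Read depth is unknown and limits the weak peaks of both lists.

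A fold of at least 10 left 13988 TSC and 26835 EVT peaks. For the overlapped share of TSC and then EVT peaks, the upper 50% of each list gave 67.1% and 32.0%, the same number of strongest peaks 49.2% and 48.7%, at least 50% of the peak covered 68.9% and 31.2%, and summits within 200 bp 68.8% and 32.9%. Shifting peaks gave a chance overlap of 1.24% and 0.589%. The ratio of median strength, shared over list-specific, was 1.73 in TSC and 2.18 in EVT with −log10 q in place of fold. Summits near a gene end made up 4.64% in TSC and 4.40% in EVT in the upper 50%, 4.39% of EVT peaks with the same number of peaks, 9.70% and 9.63% within 2.5 kb, and 10.7% and 10.2% with all annotated genes.

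Of 216 percentiles of gene lists under alternatives, 179 stayed on the same side of the limits. A place outside the middle 95% was lost by 26 and gained by 10. In 1 more case it was lost and the value passed to the other side of the random mean, still inside the middle 95%. All alternatives left 19 of 36 list results on the same side. The cause of the other changes was not tested. The number of extravillous list members with an EVT peak was at percentile 75.4 in the upper 50%, 78.8 with the same number of peaks and 79.4 at a fold of at least 10. For Hippo and TEAD those values were 93.2, 94.3 and 90.6. For epithelial-mesenchymal transition the upper 50% gave 97.7, the same number of peaks 98.2 and a limit of 10 kb 98.9. The limit of 10 kb gave 99.1 for NOTCH and TGF-beta, and any gene within 50 kb gave 96.0 for Wnt feedback genes. For members with a TSC peak, syncytiotrophoblast genes were at 87.1 with 10 kb, Wnt ligands and receptors at 95.5 in the upper 50%, and any gene within 50 kb gave 99.8 for epithelial-mesenchymal transition and 0.075 for neuron. Among genes with a peak in either list, members with an EVT peak were at 47.4 for the stem cell list, 87.5 for the extravillous list, 86.0 for syncytiotrophoblast, 82.3 for Wnt feedback, 91.3 for Wnt ligands and receptors and 76.6 for Hippo and TEAD. Except for the stem cell list (26 of 27 measured members), these EVT counts were the highest possible, so that setting could not test them. Members with a TSC peak were at 77.9 for syncytiotrophoblast, 92.7 for Wnt ligands and receptors and 94.0 for Hippo and TEAD.

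For the EVT-only minus TSC-only difference, Wnt ligands and receptors were at percentile 9.42 with the same number of strongest peaks, a reversal, and at 90.7 in the upper 50%, 97.0 with 10 kb, 74.0 with any gene within 50 kb, 70.8 among genes with a peak and 95.6 at a fold of at least 10. The stem cell list was at 7.31 in the upper 50%, 20.1 with 10 kb and 48.4 at a fold of at least 10. The extravillous list was at 97.9 in the upper 50% and 99.1 with 10 kb, but at 84.3 with any gene within 50 kb and 81.4 among genes with a peak. Wnt feedback genes were at 0.05 with any gene within 50 kb and 0.485 among genes with a peak, but at 62.7 in the upper 50%, 27.6 with the same number of peaks and 38.2 at a fold of at least 10. For the share of list-specific peaks and the number of members with an EVT and no TSC peak, 56 percentiles stayed on their side, while the stem cell list was at 5.83 with the same number of peaks, the extravillous list at 98.0 without EPAS1, and the hepatocyte list, without TTR, at 99.7 for EVT and 99.8 for TSC peaks.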

Other observations

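The genes in these paragraphs were chosen after their values were seen, except members of the gene lists and FHOD3. At 29 genes there were at least 10 EVT peaks and no TSC peak. At 28 of them no TSC summit lay inside the gene body, a check that only genes overlapping another gene can fail. No chance number was computed for the 29. Shuffled EVT-only labels gave a mean of 41.8 genes with at least 90% EVT-only peaks, so single genes named here may be high by scatter. After FHOD3 (25 EVT peaks) came TBC1D4, a regulator of glucose transporter traffic, with 16, the zinc finger gene JAZF1 with 15, GALNT2, an enzyme of protein glycosylation, with 14, and RARB, a retinoic acid receptor gene, with 13. The Wnt inhibitor gene SFRP1 was assigned 11, of which 1 lay inside the gene, and the axon guidance gene NTN1 had 10. The reverse was counted at a lower limit, at least 5 TSC peaks and no EVT peak. It held for SSH1, a cofilin phosphatase gene, with 8, the oxysterol receptor gene NR1H3 with 5, and CTXND1 with 5. At that limit 257 genes had EVT peaks and no TSC peak.

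LTBP1, NR3C1 and TGFB2 had EVT peaks that were mostly absent from the TSC list. LTBP1, which holds latent TGF-beta in the matrix, had 17 EVT peaks of which 16 were EVT only, and 1 TSC peak. NR3C1, the glucocorticoid receptor gene, had 14 EVT peaks of which 13 were EVT only, and 1 TSC peak. TGFB2 had 20, of which 19 were EVT only.

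Gene families were compared by the first letters of their symbols, a test chosen after the data were seen. Of 132 families with at least 12 members and 30 EVT peaks, the share of EVT-only peaks, with the same number of strongest peaks from each list, lay above the middle 95% of random lists for 3 and below it for 1. With no relation 3.3 would be expected on each side, so no family stood out.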
